A study of Mus musculus with 30 samples.

How the data were processed

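Total RNA from liver, kidney and brain of 10 male Avy/a mice, taken at day 22, was measured on Affymetrix Mouse Genome 430 2.0 arrays, with 1 array for each of the 30 tissue samples. Per the labels the mice fall into 5 coat classes (yellow, slightly mottled, mottled, heavily mottled and pseudoagouti) with 2 mice in each, numbered 1 and 2. The 3 arrays that carry the same class and number were taken as the same mouse. The labels give no scan date, batch or litter.

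The deposited values are linear intensity per probe set, computed by the authors with MAS5, whose version is not given. In the 30 columns the trimmed mean over probe sets was 500.0, with 2% trimmed at each end, so each array had been scaled to the same target. The file holds no detection calls. Values were used as deposited, after log2(signal + 16).

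Of 45101 probe sets, 64 controls were left out. The platform annotation gave 34945 of the others exactly 1 gene symbol, 932 several and 9160 none. A probe set was tested if the highest of its 3 tissue means was at or above the median of that quantity over all probe sets, a signal of 242, which kept 22519 probe sets and 12159 genes. No positions are given because no genome build was used.

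Models were fitted with limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend, and Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. Tissues were compared within mice, with mouse as a fixed block and a log2 difference of at least 1. The mouse effect was limma's moderated F-test on the 9 mouse coefficients with tissue as a covariate. The variation ratio R was the mean over 3 tissues of the SD across 10 mice, divided by the mean over 10 mice of the SD across 3 tissues, on log2 values. The series description names an R-value above 1.5 without its formula, so this formula was a choice. Coat slopes were fitted per step of a scale from 0 (yellow) to 4 (pseudoagouti), on each mouse's mean of 3 tissues and in each tissue. The difference of slopes between tissues was tested by the moderated F-test of the interaction. For the agouti gene, named a, the slope was tested by a two-sided exact permutation test over the 113400 assignments of 10 mice to classes.

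Gene lists were fixed before the data were examined: agouti and melanocortin signalling, genes near reported variable retrotransposon insertions, DNA methylation and retrotransposon silencing, imprinted genes, circadian clock, glucocorticoid and fasting response, immediate early genes, heat shock chaperones, interferon response, MHC and antigen presentation, genes that often vary by strain background, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and PPAR alpha targets, gluconeogenesis and insulin signalling, hypothalamic feeding peptides, oxidative stress and drug metabolism, cell cycle, X inactivation and Y chromosome genes, and 11 marker lists (liver, kidney, brain, blood and erythroid, lymphoid and myeloid, adipose, adrenal, skeletal muscle, pancreas, pituitary, choroid plexus and ependyma). Each gene stood in a list by its probe set with the highest mean over all arrays, while named genes outside the lists could have another probe set. Of these 30 lists, 26 had at least 3 measured members and were tested. On coat slopes the test was camera with a preset correlation of 0.01, repeated with an estimated correlation, adjusted over 104 tests. On the mouse effect it was the mean log F of the members against 100000 shuffles of mice within tissues.

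Named genes followed a rule fixed before the data were examined. It took, from probe sets with 1 symbol, the 8 genes per tissue with the largest smaller difference from the other tissues, the 20 with the smallest p in the mouse F-test, the 20 with the largest R, the 5 with the smallest p per direction in each coat fit, up to 4 members per list, the gene a, and Xist with Y-linked genes as a check of sex. Clock members beyond those 4, the example transcripts of other tissues and the genes of the interaction with a mouse left out were chosen after their values were seen.

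The alternatives tried were offsets of 1 and 64, no filter, a filter on the overall mean, quantile normalisation over all arrays or within tissue, probe sets without shared-sequence suffixes, the replicate number as a block, a random mouse block by duplicateCorrelation, unordered classes, the 3 prime over 5 prime Gapdh ratio as a covariate, pairs of tissues, an F-test without moderation, other formulas and thresholds of R, and each mouse left out. Removal of the replicate number within each tissue, the highest signal of each array as a covariate, marker means as covariates and the joint omission of some mice were added after the data were seen.

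The fits were tested on simulated data with the residual spread of these arrays and 200 changed probe sets. A mouse SD of 0.5 log2 was recovered in 66.0% of them, and in 64.5% with the replicate number removed within tissue. A coat slope of 0.25 per step was recovered in 81.5% for the mean of tissues, 22.5% in liver, 21.5% in kidney and 22.5% in brain. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.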

Results

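Expression was measured in liver, kidney and brain of 10 male mice that carry the viable yellow allele of the agouti gene, Avy, opposite a nonagouti allele. In Avy a retrotransposon upstream of the gene can drive its transcription in many tissues, and the coat ranges from yellow through mottling to pseudoagouti, which looks like wild-type agouti. There were 2 mice in each of 5 coat classes and 10 arrays per tissue. The median signal per array was 105.2 to 144.6 in liver, 114.2 to 152.6 in kidney and 138.2 to 205.4 in brain, and the highest signal was 34084 to 50092, 19007 to 45410 and 16761 to 37230. The Y-linked genes Eif2s3y, Kdm5d and Uty had mean signals of 1001 ± 531, 409 ± 99.4 and 602 ± 217 (SD, n = 30) at their strongest probe sets, while the 3 probe sets of Xist, the X-inactivation RNA, had means of 8.38, 11.04 and 190.4.

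After tissue means were removed, the first principal component held 18.3% of the variance and ran with the number in the mouse labels. It was below 0 in 5 of 5 liver, 4 of 5 kidney and 3 of 5 brain arrays of mice numbered 1, and above 0 in 5 of 5 arrays of mice numbered 2 in each tissue. In kidney and brain the sign of the component also ran with the highest signal of the array. Kidney arrays below 0 had 36951 to 45410 and those above 0 had 19007 to 25922. Brain arrays below 0 had 34204 to 37230 and those above 0 had 16761 to 24161. In liver the highest signal overlapped, at 39228 to 47341 for number 1 and 34084 to 50092 for number 2. The 2 numbers are balanced over coat classes.

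**Figure D1:**
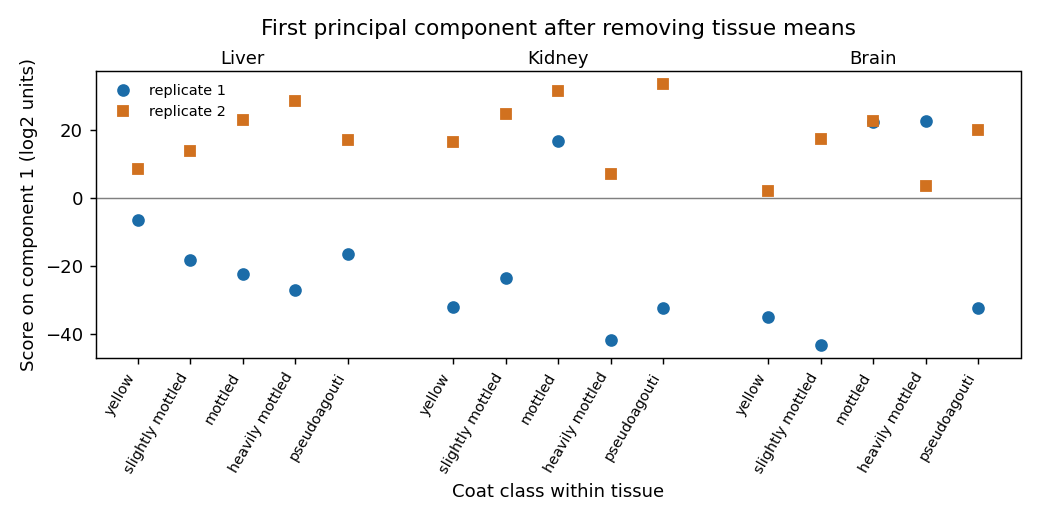
Score of each of 30 arrays on the first principal component of log2 signal after tissue means were removed, by coat class within tissue. Circles are mice numbered 1 and squares mice numbered 2; the squares are above 0 in each tissue and the circles below 0 except for 1 kidney and 2 brain arrays.

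The first comparison asked which transcripts distinguish the tissues, as a check of the tissue labels and of the scale on which mice were compared. The folds of single genes are ratios of signal + 16 and are lower bounds, because the other tissues were near background for most of these genes. Fgb, the fibrinogen beta chain, was at 15.01 ± 0.22 in liver against 5.32 ± 1.48 in kidney and 4.25 ± 0.11 in brain (log2 mean ± SD, n = 10), at least 824-fold above the nearer tissue. Arg1, the arginase of the urea cycle, was at least 484-fold higher, the carboxylesterase Ces1c 603-fold, the steroid dehydrogenase Akr1c6 537-fold and the cytochrome P450 Cyp3a25 511-fold. The lipoprotein components Apof and Apoc4 and the major urinary protein Mup3 were at least 488-fold, 473-fold and 495-fold higher.

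Kidney expressed Kap, the androgen-regulated protein of the proximal tubule, at 14.78 ± 0.44, at least 686-fold above the nearer tissue. Umod, the uromodulin of the thick ascending limb, was at least 425-fold higher, the tubular cadherin Cdh16 426-fold, the endocytic receptor megalin (Lrp2) 289-fold and the tissue kallikrein Klk1 665-fold. The calcium-binding protein S100g, the nuclease Dnase1 and the aspartic protease Napsa were at least 457-fold, 291-fold and 282-fold higher.

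Brain expressed Snap25, which drives fusion of synaptic vesicles, at 14.14 ± 0.30, at least 713-fold above the nearer tissue. The myelin genes Mobp and Mbp were at least 660-fold and 656-fold higher. Gad1, which makes the transmitter GABA, was at least 224-fold higher, the neurofilament gene Nefl 261-fold, the vesicle GTPase Rab3c 225-fold, the calcium sensor Hpcal4 280-fold and Fgf13, which binds neuronal sodium channels, 254-fold. Each of these 24 genes was higher in its tissue in 10 of 10 mice, with adjusted p of 1.00e-16 or less in limma. Of the marker lists, 16 of 16 liver, 16 of 16 kidney and 17 of 17 brain genes were higher in their own tissue than in both others.

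In total 2218 of 22519 probe sets were higher and 4191 lower in liver than in kidney, 4605 higher and 6800 lower in liver than in brain, and 4669 higher and 4927 lower in kidney than in brain. Higher than in both other tissues were 1621 probe sets in liver, 1648 in kidney and 4335 in brain. The median log2 difference of all probe sets was -0.13, -0.15 and 0.03 in these contrasts, and -0.02, 0.11 and 0.13 after quantile normalisation over all arrays. With it 2587 were higher and 3571 lower in liver than in kidney, 5673 and 5852 in liver than in brain, and 5108 and 4578 in kidney than in brain, and with a filter on the overall mean the last contrast gave 4274 and 3593, so the balance of directions depends on scaling and filter.

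The second comparison addressed the aim stated for the series, a search for candidate metastable epialleles, loci whose expression varies between individuals but is shared by the tissues of an individual. The gene with the strongest shared mouse effect was Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce. It ranged 3.84-fold from mottled 2 to yellow 2 (1.94 log2, residual SD 0.30, n = 10 mice, adjusted p = 4.80e-05). Next were Nfkbia, the inhibitor of NF-kappaB, with a range of 2.83-fold, and the hormone-responsive factor Klf9 with 3.05-fold. Slc22a30, of the organic anion transporter family, had 6.30-fold, Gm6958 4.24-fold, the kinase Pim3 3.01-fold and the dynein light chain Dynll1 2.08-fold.

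Of the other genes named by the rule, the forkhead factors Foxo3 and Foxp1 ranged 2.40-fold and 2.84-fold, and the sestrin Sesn1 3.11-fold. The inositol phosphate kinase Ip6k2 ranged 3.39-fold. The transcription cofactors Dr1 and Eny2 ranged 1.87-fold and 3.01-fold. The SNARE protein Snap23, the sorting protein Vps36 and the endocytic protein Fcho2 ranged 2.51-fold, 1.97-fold and 1.97-fold. The actin-binding Lasp1 and Klhl2 and the gamma-tubulin partner Mzt1 ranged 2.36-fold, 2.35-fold and 1.91-fold, and the sodium pump subunit Atp1b3 1.75-fold.

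The moderated F-test called 1531 of 22519 probe sets (1253 genes, 6.80%). With the replicate number removed within each tissue 94 were called, of which 91 were among the 1531, and with the number as a block over all tissues, the alternative planned beforehand, 41. Liver and kidney alone gave 412, kidney and brain 699 and liver and brain 1. Of the 20 named genes 16 were higher in mice numbered 2, and 6 were called with the number removed: Fkbp5 (adjusted p = 0.00529), Slc22a30 (0.0296), Gm6958 (0.00529), Lasp1 (0.0392), Dynll1 (0.0178) and Pim3 (0.00529). With the highest signal of each array as a covariate 121 were called. The count was 962, 909, 786, 925, 665 and 866 without yellow 1, slightly mottled 1, pseudoagouti 1, yellow 2, mottled 2 and pseudoagouti 2, and 2745 with mottled 1 and heavily mottled 1 both left out.

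Among the fixed lists, circadian clock genes varied between mice. Of 16 measured members 9 were called over all genes tested and 10 adjusted over the list alone, and 4 with the number removed. Arntl, which encodes the BMAL subunit of the activator of the clock, ranged over 1.86 log2 (highest in mottled 1, lowest in pseudoagouti 1). Its partner Npas2 ranged over 2.53 log2, and the repressors Per2 and Nr1d2 over 1.83 and 1.27. The other called members were Per1, Nr1d1, Ciart, Tef and Hlf. Dbp was not called at the probe set that stands for it in the list (adjusted p = 0.0580), while its other probe set was (0.00208). The list passed with adjusted p = 5.2e-05 from permutation, and with adjusted p = 0.00039 after removal of the number.

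**Figure D2:**
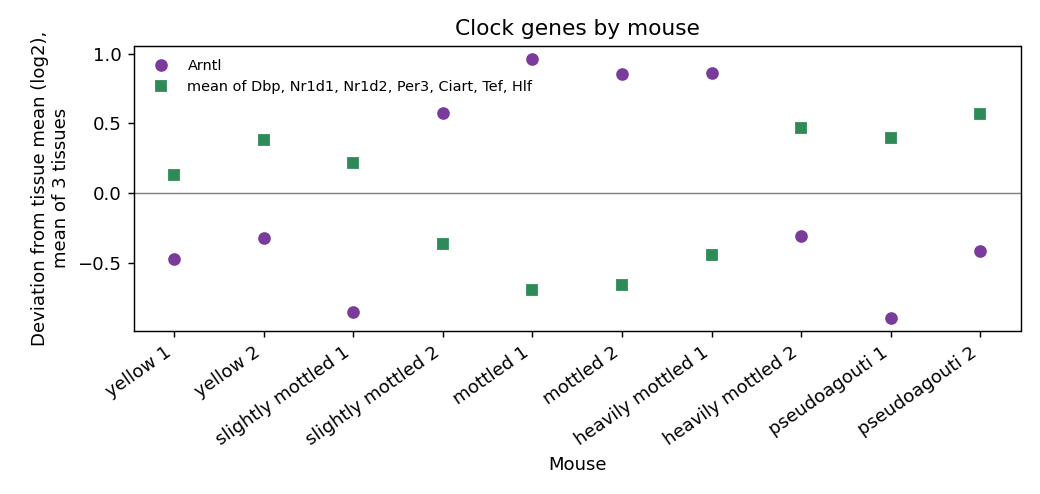
Deviation of Arntl and of the mean of Dbp, Nr1d1, Nr1d2, Per3, Ciart, Tef and Hlf from their means over mice, for each of 10 mice (log2, mean of 3 tissues). The 2 measures are on opposite sides of 0 in 10 of 10 mice.

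Glucocorticoid and fasting response genes passed with 7 of 18 members over all genes tested and 11 adjusted over the list alone, 1 of them (Fkbp5) with the number removed. The transcription factors Zbtb16 and Cebpd ranged over 3.12 and 1.96 log2, and all 7 were higher in mice numbered 2. Heat shock chaperones passed with 7 of 16 and 11 adjusted over the list alone, all 7 higher in mice numbered 1, with 3 called after its removal. Those 3 were Dnajb1, a co-chaperone of Hsp70 proteins, with a range of 1.14 log2, Chordc1 with 1.09 and Hspa5 with 0.77. The adjusted p of both lists was 5.2e-05, and 0.00026 with the number removed; raw p of 1e-05 was the smallest that the shuffles could give.

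Of 26 lists 20 passed, 17 with the number removed and 13 without heavily mottled 2. The test set each list against shuffled mice and not against other genes. Of all probe sets tested 6.80% were called, and 0.42% with the number removed. A list could therefore pass without more called members than other genes had. In the following, 3 counts per list give the members called over all genes tested, adjusted over the list alone, and over all genes with the number removed. Fatty acid oxidation and PPAR alpha targets had 4, 7 and 1, the last being Ehhadh of peroxisomal oxidation with a range of 1.12 log2, and cholesterol synthesis had 4, 7 and 3, among them the squalene synthase Fdft1 (1.56). The cell cycle had 2, 8 and 0, gluconeogenesis and insulin signalling 2, 2 and 0 (Foxo3 and Igfbp1), and MHC and antigen presentation 2, 2 and 1 (H2-Eb1 kept, H2-Ab1 lost). Genes that often vary by strain background had 2, 5 and 0 (Rps4l and Cap1) and the Y-linked genes Eif2s3y, Uty and Kdm5d 3, 3 and 0. The agouti list and the retrotransposon insertion list each had 1, 1 and 1, the gene a itself. The permutation adjusted p was 0.0140 for the agouti list and 5.2e-05 for the retrotransposon insertion list. With the number removed it was 0.0112 and 0.00039. No test of either list without a is given here. DNA methylation and retrotransposon silencing had 1, 1 and 0 (Atrx), lymphoid and myeloid markers 1, 2 and 0 (Lyz2), fatty acid synthesis 1, 3 and 0 (Mlxipl), interferon response 1, 2 and 0 (Ifit3), and blood and erythroid markers 0, 2 and 0. Choroid plexus, adipose, and oxidative stress and drug metabolism lists passed with 0, 0 and 0.

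Of the lists that still passed with the number removed, Y-linked genes and adipose markers were close to the threshold (permutation adjusted p = 0.0486 each). So were DNA methylation and retrotransposon silencing, cholesterol synthesis, and oxidative stress and drug metabolism (0.04998 each). With the number removed, choroid plexus (adjusted p = 0.0752), blood and erythroid (0.133), fatty acid synthesis (0.152) and interferon response (0.122) no longer passed, and imprinted genes did (0.0486). Without its removal imprinted genes missed the threshold with 1, 3 and 0 (Mirg, adjusted p = 0.271), immediate early genes with 2, 2 and 1 (Fos lost, Zfp36 kept, 0.265) and hypothalamic feeding peptides with 1, 1 and 0 (Lepr, 0.526). Liver markers (0.503) and kidney markers (0.350) had 0, 0 and 0 and brain markers (0.578) 1, 1 and 0 (Gfap). Adrenal, skeletal muscle and pancreas markers had 2 measured members each and pituitary markers 0, too few for a test.

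The ratio R ranked genes by variation between mice over variation between tissues. Psme3, a proteasome activator, had the highest R of 2.10, then Hnrnpul1, which binds RNA, with 2.09, Abi1, of the actin-regulating WAVE complex, with 2.07, and Dnajb1 with 2.06. The cyclin Ccni had 1.96, the chaperonin subunit Cct3 1.95, seipin (Bscl2) 1.95, the mitochondrial ubiquitin ligase Mul1 1.93, Tsr3 of ribosome maturation 1.91 and the glycolytic enzyme Tpi1 1.91. Syncrip, which binds RNA, had 1.90, and the splicing factors Sf3a3 and Sfpq 1.87 each. Klhl9, Ndufs5 of respiratory complex I, Pdzd8, Srd5a3 of dolichol synthesis, the spliceosomal helicase Snrnp200 and the chromatin protein Baz1b had 1.86, 1.86, 1.86, 1.84, 1.82 and 1.80. The agouti gene a had R of 1.89, rank 13 among probe sets, and 2.11 with the number removed, rank 3.

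In all, 149 of 22519 probe sets (130 genes) had R above 1.5, and 107 of them were also called in the mouse F-test. Of these 107, 11 were also called in the F-test with the number removed, where R itself was taken without its removal. Of the 20 named genes 2, Dnajb1 and a, were called in the F-test with the number removed. With the number removed within tissue 81 exceeded 1.5, 41 of them in common, and with the highest signal removed 42. Of the 20 named genes 7 stayed above 1.5 with the number removed, among them Dnajb1 at 2.30, Sf3a3 at 1.78 and Psme3 at 1.63. Another probe set of Dnajb1, which stands for it in the heat shock list, had R of only 1.10, and 1.10 with the number removed. The count was 302 with mottled 1 and heavily mottled 1 both left out, and it depended on the formula, with 55 probe sets for pooled variances and 1067 for the SD of means.

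The third comparison asked which transcripts follow the coat. The agouti gene a, whose product blocks melanocortin receptors and turns pigment yellow, was highest in yellow mice and lowest in pseudoagouti mice in each tissue except liver, where mottled mice had the highest mean. In kidney its mean signal was 688 ± 47.6 in yellow, 402 ± 96.4 in slightly mottled, 349 ± 60.0 in mottled, 199 ± 101.3 in heavily mottled and 90.7 ± 14.6 in pseudoagouti mice (SD, n = 2 each). In means of log2(signal + 16) yellow exceeded pseudoagouti 6.63-fold in kidney, 3.09-fold in brain and 2.68-fold in liver.

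**Figure D3:**
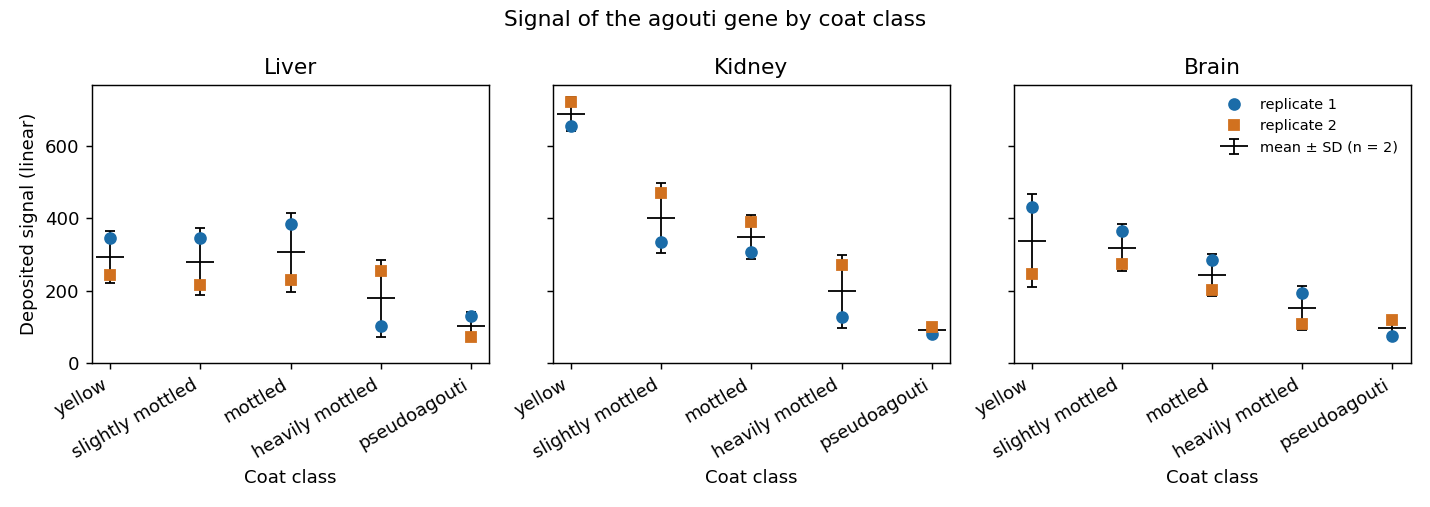
Deposited linear signal of the agouti gene a by coat class in liver, kidney and brain; points are single mice and bars the mean and SD of 2 mice. Kidney means fall from 688 in yellow to 90.7 in pseudoagouti mice.

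The slope of a per coat step was -0.65 ± 0.078 log2 (SE, n = 10 mice) in kidney, -0.43 ± 0.084 in brain, -0.35 ± 0.106 in liver and -0.48 ± 0.058 in the mean of tissues. The two-sided exact permutation p was 5.29e-05 in kidney, 0.00145 in brain, 0.0198 in liver and 5.29e-05 in the mean, and adjusted over the 4 tests 1.06e-04, 0.00193, 0.0198 and 1.06e-04. With assignments permuted within the replicate number, the exact p was 1.39e-04, 6.94e-04, 0.0371 and 1.39e-04. The 58 alternatives kept the direction, and 57 kept the p under 0.05; without pseudoagouti 2 the liver slope was -0.26 with an exact p of 0.0753. Between tissues of a mouse the log2 signal of a had a Pearson r of 0.772 for liver and kidney (permutation p = 0.00997, adjusted 0.0162), 0.677 for liver and brain (0.0312, adjusted 0.0312) and 0.763 for kidney and brain (0.0108, adjusted 0.0162), over 3 relations and 10 mice. Spearman's rho was 0.479, 0.673 and 0.721 (permutation p = 0.165, 0.0372 and 0.0228, adjusted 0.165, 0.0558 and 0.0558). Without the 2 extreme mice r was 0.592, 0.791 and 0.480, and within numbers 1 and 2 it was 0.865 and 0.846, 0.776 and 0.445, and 0.935 and 0.809.

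Across all probe sets a was the single call of limma, for the mean of tissues (adjusted p = 0.0294) and for kidney (adjusted p = 0.0338), with 428 and 465 probe sets at unadjusted p under 0.05. Liver and brain gave 0 calls in limma, with 536 and 326 at unadjusted p under 0.05. The call of a was kept in 3 of 10 fits with a mouse left out, for the mean without mottled 1, yellow 2 or heavily mottled 2 and for kidney without slightly mottled 1, mottled 2 or heavily mottled 2, and its adjusted p rose to at most 0.325 and 0.348 without the others. With the 3 prime over 5 prime Gapdh ratio as a covariate the slopes were -0.47 and -0.67 with adjusted p of 0.114 and 0.0656.

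The genes ranked behind a did not pass in limma, and their adjusted p was near 1. Toward pseudoagouti the mean of tissues was lower for Apoa1, an apolipoprotein (slope -0.33 ± 0.065), the zinc finger gene Zfp235 (-0.25 ± 0.054), Rnf227 (-0.19 ± 0.045) and the ribonucleotide reductase subunit Rrm2 (-0.26 ± 0.061). It was higher for Ttc36 (0.16 ± 0.037), the cadherin Celsr3 (0.23 ± 0.057), 9330159F19Rik (0.19 ± 0.049), Apmap (0.16 ± 0.048) and the protocadherin Pcdh10 (0.17 ± 0.050). In kidney the lowest p values after a belonged to Unc45a (-0.30), Ppp1r3b, a glycogen-targeting phosphatase subunit (-0.72), Apoa1 (-1.01) and the coagulation factor F7 (-0.48), of which Apoa1 and F7 are typical liver transcripts and the liver marker mean in kidney had a slope of -0.34, and in the other direction to Apmap, Azin2, Celsr3, Pstpip2 and Pcdh10 (0.37, 0.35, 0.35, 0.39 and 0.33). In liver they were Zfp235, Plch2, Usp9x, Baiap2 and Hspb3 (-0.56, -0.43, -0.24, -0.39 and -0.48) and 9330159F19Rik, Ddn, Deptor, Txnip and Slc6a11 (0.43, 0.46, 0.19, 0.23 and 0.40). In brain they were a, Fcer1g, St6galnac5, Cpne6 and Cldn2 (-0.43, -0.25, -0.31, -0.26 and -0.70) and Syne1, Mpp7, Myef2, Zfp207 and Cdcp1 (0.15, 0.36, 0.18, 0.20 and 0.27).

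Cell cycle genes were lower toward pseudoagouti as a list, in 15 of 16 members for the mean of tissues (camera adjusted p = 4.80e-10; with an estimated correlation adjusted p = 0.248), 15 of 16 in liver (2.72e-08; estimated 0.394) and 16 of 16 in kidney (6.05e-05; estimated 0.526), and were not called in brain, with 9 of 16 lower (0.155). Cdk1, the mitotic kinase, had a slope of -0.19 ± 0.058 in the mean and Mki67, the proliferation marker, -0.18 ± 0.078, and neither passed alone. Members past the threshold over all genes tested and adjusted over the list alone numbered 0 and 0 in each fit. In the same arrays liver and adipose markers had mean slopes of -0.34 and -0.42 in kidney, and erythroid markers 0.18 in liver. The brain mean of the cell cycle list was lowest in pseudoagouti 1, at 6.88 against 7.26 for the next mouse. In the mean of tissues cholesterol synthesis genes fell in 16 of 17 members (4.17e-04; with an estimated correlation adjusted p = 0.526), and in brain in 16 of 17 (6.02e-07; estimated 0.248), with Hmgcs1 at -0.10 ± 0.059 and Mvk at -0.11 ± 0.059; in the same brain arrays choroid plexus markers had a mean slope of -0.39 and brain markers -0.07. Fatty acid synthesis genes fell in 14 of 17 in the mean (0.00551; estimated 0.402), 12 of 17 in kidney (0.0452; estimated 0.537) and 15 of 17 in brain (0.00221; estimated 0.402), with Fasn, the fatty acid synthase, at -0.28 ± 0.098 in kidney, where the adipose marker mean also varied between mice, from 7.58 to 11.58, with a slope of -0.42. Fatty acid oxidation and PPAR alpha targets rose in 13 of 17 in the mean (0.0227; estimated 0.404) and in kidney (0.00430; estimated 0.404), with the thioesterase Acot2 at 0.14 ± 0.062 in kidney. These metabolic lists had 0 and 0 members over all genes tested and adjusted over the list alone.

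Immediate early genes, which neuronal activity and growth factors induce, fell in 11 of 15 members in the mean (0.0227; with an estimated correlation adjusted p = 0.248), 11 of 15 in kidney (0.0452; estimated 0.537) and 12 of 15 in brain (4.31e-05; estimated 0.248). In kidney slightly mottled 2 stood apart in the mean of this list, at 9.48 against 8.98 for the next mouse, and in the brain arrays the mean slope of choroid plexus markers was -0.39 and that of brain markers -0.07. In brain Arc, a synaptic activity gene, had -0.37 ± 0.12, Junb -0.18 ± 0.057 and Nr4a1 -0.22 ± 0.087. Interferon response genes rose in 15 of 19 in liver (0.00237; estimated 0.526), with the antiviral genes Oas1a at 0.20 ± 0.059 and Rsad2 at 0.23 ± 0.084. Erythroid markers rose in 3 of 3 in liver (0.0106; estimated 0.248) and kidney (0.0120; estimated 0.248), with Alas2 of heme synthesis at 0.34 ± 0.16 in liver. Imprinted genes fell in 14 of 21 in the mean (0.0247; estimated 0.402), with Nnat at -0.17 ± 0.058, and heat shock chaperones in 14 of 16 in brain (0.0286; estimated 0.588). Y-linked genes rose in 3 of 3 in the mean (0.0390; estimated 0.526) and in brain (0.0160; estimated 0.404). Each of these had 0 and 0 members over all genes tested and adjusted over the list alone. The agouti list was called lower in the mean (0.0227; estimated 0.248) and kidney (0.00333; estimated 0.248), with 3 of 5 members lower, a median slope of -0.0054 in the mean and a as its 1 member past both, and in liver and brain, where the list was not called, a passed adjusted over the list alone. The retrotransposon insertion list fell in 6 of 9 in the mean (0.0390; estimated 0.248) and 5 of 9 in kidney (0.0380; estimated 0.248), with 1 member over all genes tested (a) and in kidney 2 adjusted over the list alone (a and Cdk5rap1, at -0.20 ± 0.065).

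Among the marker lists, liver markers fell in 14 of 16 members in kidney (2.15e-08; with an estimated correlation adjusted p = 0.264) and 13 of 16 in the mean (2.14e-07; estimated 0.342). In kidney 0 passed over all genes tested and 6 adjusted over the list alone, among them albumin (Alb, -0.85 ± 0.28), Fgb (-0.76 ± 0.19) and Cps1 of the urea cycle (-0.65 ± 0.16), and in the mean the counts were 0 and 2 (Apoa1 and Fgb). Liver markers were higher in 15 of 16 members in liver and 10 of 16 in brain, so their fall in the mean came mostly from kidney. The kidney array of yellow 2 had a liver marker mean of 10.07, and the others 7.40 to 8.73. Choroid plexus and ependyma markers fell in 9 of 9 in brain (3.86e-14; estimated 0.248), with 0 and 7 members, among them the tight junction gene Cldn2 (-0.70 ± 0.18) and the FGF co-receptor gene Kl (-0.46 ± 0.15), and in 9 of 9 in the mean (2.14e-07; estimated 0.248), with 0 and 2. Their mean slope was 0.0075 in kidney and -0.02 in liver, so the fall in the mean came mostly from brain. Adipose markers fell in 6 of 6 in kidney (0.00479; estimated 0.526), with 0 and 0, and the exact permutation p of their mean was 0.263 (adjusted 0.591). Brain markers fell in 14 of 17 in brain (0.00507; estimated 0.526), with 0 and 0, Gfap of astrocytes at -0.24 ± 0.14.

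Camera called 11 of 26 lists in the mean, 3 in liver, 9 in kidney and 7 in brain, and 0 in each with an estimated correlation, although the mean, median and test had a common sign in each called list. The lists without a call in any fit were circadian clock, glucocorticoid and fasting response, DNA methylation and retrotransposon silencing, MHC and antigen presentation, genes that often vary by strain background, gluconeogenesis and insulin signalling, hypothalamic feeding peptides, oxidative stress and drug metabolism, kidney markers, and lymphoid and myeloid markers. Of these the oxidative stress list had 0 members over all genes tested and 2 adjusted over the list alone in kidney (Cyp3a11 and Cyp1a2), with a mean slope of -0.08 and a lower test direction but a median of 0.0045.

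The difference of coat slopes between tissues was tested directly. Limma's interaction F-test called 0 of 22519 probe sets, with 544 at unadjusted p under 0.05. For a the kidney slope lay 0.65 below 0 and the liver slope 0.35 below 0, a difference of -0.30, and the interaction F-test over the slopes of all 3 tissues gave an unadjusted p of 0.0718. Apoa1 was called without mottled 1 (adjusted p = 0.0166, kidney minus liver slope -1.04), and a probe set with no symbol without pseudoagouti 1 (adjusted p = 0.00695). Another probe set of Apoa1, a liver transcript, had a signal of 1698 in the kidney of yellow 2 against 7.2 to 533 in the other kidneys. Of abundant liver probe sets that were low in the other kidneys, 106 of 106 were above the others' median there, a choice that limited the other kidneys but not yellow 2. Of 361 liver probe sets chosen by liver and brain level alone, 259 were above the median kidney in yellow 2. Of the list means 0 differed between tissues by exact permutation, the agouti list in kidney against brain coming closest (exact p = 0.00395, adjusted 0.173).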

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

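The tests of the calls left with the number removed, of the clock genes and of single liver transcripts in kidney were chosen after the result was seen, as was the test of the number for the liver markers. The regroupings of samples, the other partitions of mice and the rank test across liver transcripts were set before their own results were seen. Those that remove the number within each tissue rest on a step that was itself added after the data were seen.

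Of 94 groups of 10 values, 6 held a value far from the others, and chance gives about 1 in 20 groups. Liver markers in kidney were highest in yellow 2, at 10.07 against 8.73 for the next mouse. Immediate early genes in kidney were highest in slightly mottled 2, at 9.48 against 8.98. Fatty acid oxidation and PPAR alpha targets in brain were highest in heavily mottled 1, at 8.70 against 8.39, and kidney markers in brain were highest in the same mouse, at 7.44 against 7.03. Cell cycle genes in brain were lowest in pseudoagouti 1, at 6.88 against 7.26. The log2 ratio of the 3 prime over 5 prime Gapdh control probe sets in kidney was highest in pseudoagouti 2, at 0.0214 against -0.28.

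Liver transcripts in the kidney array of yellow 2 may be liver RNA carried over at dissection or later, a hypothesis found in these data. Of 106 probe sets with a liver signal of at least 10000 and a median under 200 in the other kidneys, 100% were above that median in yellow 2, by a median of 1.04% of the liver signal (quartiles 0.62% and 1.43%), while the other mice had 11 to 90 above. The choice of these probe sets limited the level in the other kidneys but not in yellow 2, so its count is not like for like with theirs. Alb was at 10094 against 151 to 4378 in the other kidneys, Apoa1 at 1698 against 7.2 to 533, Ahsg at 1313 against 5.3 to 358 and Cps1 at 1151 against 24.6 to 251. Fgb was at 294 against 1.5 to 88.9. The liver signals of these genes were 27508, 33150, 34807, 28654 and 33268, so all but Fgb rose by a larger share than the upper quartile. The share was uneven between these genes, largest for Alb and smallest for Fgb, so 1 common share does not describe them. Alb, with a median of 677 in the other kidneys, was not among the 106. Over the 361 liver probe sets chosen by liver and brain level, 259 were above the median kidney, with a median rise of 0.57% of the liver signal. The test set beforehand, over 361 liver probe sets, gave a Spearman rho of 0.405 across probe sets, which are not independent replicates, and that lay between its bounds; 5 of the 16 markers (Ttr, Cyp2e1, Hpd, Alb and Fga) had a median kidney signal of at least 200, whose source was not tested, and 2 markers, Ttr and Tat, stand in other lists. Yellow 2's marker mean lay 1.42 above the highest of the other 4 replicate 2 kidneys, which spanned 1.07, so the replicate 2 kidneys did not stand together. Yellow 2 was singled out by this same mean, so the gap cannot decide on a difference between array sets. An effect on this array alone was not tested. Expression of these genes by the kidney of this mouse, with its yellow coat, stays open and untested.

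The fall of the mouse calls from 1531 to 94 when the replicate number was removed is what a difference between array sets that runs with the number would give. Of 99 other partitions of the 10 mice into 5 and 5, 0 left as few (175 to 2001, median 1222). In simulation the correction itself lowered recovery from 66.0% to 64.5%. That simulation drew noise independently for each probe set, so it does not measure the loss on these arrays, which may be larger. The 94 calls that were left exceed the highest of the shuffles within number, 1, so the number alone does not account for them. In highest signal and on the first component, mottled 1 in kidney and brain and heavily mottled 1 in brain lay with mice numbered 2. A difference between array sets that crosses the number in this way was not removed and stays open for the 94. What differed between the numbers is not in the labels, and litter, dam or day of collection stay open as biological or technical sources for either part.

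Clock genes may differ because mice were at different phases of the clock when tissue was taken, a hypothesis from these data. Arntl and the mean of Dbp, Nr1d1, Nr1d2, Per3, Ciart, Tef and Hlf, which peak near opposite times of day, deviated to opposite sides in 10 of 10 mice with the number removed for the mean of tissues, 10 in liver, 10 in kidney and 9 in brain, and in 10 of 10 in each tissue without its removal (exact p = 0.00476, 0.00476 and 0.00397 in liver, kidney and brain, adjusted 0.00476 each). Arntl was 0.57 to 0.96 above its mean in slightly mottled 2, mottled 1, mottled 2 and heavily mottled 1 and 0.31 to 0.89 below it in the other 6, so the mice form separate clusters and no correlation is given. Against array sets that run with the number as the whole cause stands the permutation adjusted p of 0.00039 with the number removed. Array sets that cross the number were not tested. Mottled 1 and heavily mottled 1, whose brain arrays lay with mice numbered 2, had the highest Arntl (0.96 and 0.86). The time of collection is not in the labels, so other causes of a shared shift of clock genes stay open.

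Random regroupings of the samples gave the following. Swaps of tissue labels within mice gave as many calls in 1, 1 and 1 of 100, the real labels being that 1, with at most 5071, 9672 and 8015 in the others against 6409, 11405 and 9596, so chance can be excluded. For the mouse effect (1531, highest other 1), the mouse effect with the number removed (94, highest other 1) and R above 1.5 (149, highest other 32) 1 of 100 shuffles, the real one, was as large, and chance can be excluded. Shuffles within number alone gave up to 1051 calls and up to 140 probe sets with R above 1.5, which points to a structure of the samples by number. For the coat slope 3 of 100 assignments, the real one among them, gave at least the 1 call of the mean (highest other 1) and 3 of 100 that of kidney (highest other 3). Although this is under the bar of 5 of 100 set beforehand, other assignments gave as many calls or more. They were not balanced over the replicate number as the real classes are. Each call was also kept in only 3 of 10 fits with a mouse left out, so chance is not excluded for these counts. For the 0 calls of liver, brain and the interaction (536, 326 and 544 at unadjusted p under 0.05 in limma) 100 of 100 were as large, with highest others of 2, 2 and 41; any assignment gives at least 0, so this says nothing about chance.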

How the results depend on the processing

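The number removed within each tissue, the highest signal as a covariate, the marker covariates and the joint omission of mice were tests chosen after the data were seen. The 3 tissue counts stayed within 1.5 times under the 8 alternatives (5426 to 8833, 9765 to 15197 and 7867 to 12757). With a mouse left out they ran from 6350 to 6518 for liver minus kidney, 11363 to 11509 for liver minus brain and 9555 to 9665 for kidney minus brain. The mouse effect (1531) gave 940 with no filter, 41 with the number as a block, 412, 1 and 699 for liver and kidney, liver and brain and kidney and brain alone, 882 without moderation, 94 with the number removed within tissue, 121 with the highest signal as covariate, 2745 without mottled 1 and heavily mottled 1, and 665 to 2064 with a mouse left out. R above 1.5 (149) gave 362 with no filter, where more probe sets were tested, 1855, 685 and 1771 for those tissue pairs, 55 for pooled variances, 1067 for SD of means, 4 above a threshold of 2, 81 and 42 with the number and with the highest signal removed, 302 without those 2 mice, and 132 to 215 with a mouse left out. The coat call of the mean (1) went to 0 with an offset of 1, the Gapdh ratio, unordered classes, yellow against pseudoagouti alone, and without those 2 mice, and that of kidney (1) to 0 with the Gapdh ratio, unordered classes, yellow against pseudoagouti alone and without both yellow mice; both ran from 0 to 1 with a mouse left out, liver and brain stayed at 0, and the interaction ran from 0 to 1. Slopes of a ran from -0.53 to -0.45 in the mean, -0.42 to -0.26 in liver, -0.68 to -0.60 in kidney and -0.52 to -0.37 in brain with a mouse left out. In kidney the slope was -0.64 (exact p = 7.76e-04) with the liver markers and -0.66 (7.06e-05) with the adipose markers as covariate, and with a random mouse block over all arrays (correlation 0.16) the adjusted p of a was 0.00102. Calls of lists ran from 21 to 34 for the coat (30), the lowest without pseudoagouti 2, and 13 to 19 for the mouse effect (20), the lowest without heavily mottled 2. The cause was not tested. The difference between mice 1 and 2 of a class, across probe sets, had r above 0.1 with that of another class in 10 of 10 pairs of classes in liver, 9 in kidney, 6 in brain and 9 in the mean. Of the named genes, 426 of 426 tissue comparisons, 780 of 798 coat, 415 of 475 mouse and 479 of 516 R comparisons kept their side of the threshold, 348 of 420 for lists on the coat, and 0 reversed. Low signals carry background that the offset damps, and no detection calls were used.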

Other observations

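The tests of marker list means against the coat were chosen after the result was seen.

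Adipose markers varied widely between kidney samples. Their mean log2 signal ran from 7.58 in slightly mottled 1 to 11.58 in heavily mottled 1. Adipoq, the hormone of fat cells, ran from 3.4 to 3083, Ucp1, the uncoupling protein of brown fat, from 3.0 to 5276, and Car3, abundant in fat and muscle, from 274 to 16126. The coat slope of the list mean was -0.42 with an exact permutation p of 0.263 (adjusted over 9 tests 0.591). In liver the same list had a slope of 0.08 with an exact p of 0.0444 (adjusted 0.133).

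Choroid plexus markers varied between brain samples, with a mean log2 signal from 7.06 in mottled 1 to 9.32 in yellow 2. Ttr, the thyroxine carrier made by the choroid plexus and liver, ran from 373 in mottled 1 to 31779 in yellow 1, Cldn2 from 8.0 to 278, Kl from 46.9 to 532 and Sostdc1 from 48.3 to 761. The slope of the list mean was -0.39 with an exact p of 0.0318 (adjusted 0.133), and that of liver markers in kidney -0.34 with an exact p of 0.0411 (adjusted 0.133), so 0 of the 9 passed.

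Among the genes called between mice with the number removed, Dbp, an output factor of the clock, ranged over 3.02 log2 from mottled 2 to pseudoagouti 1 and the organic anion transporter Slco1a1 over 3.28 log2 from slightly mottled 2 to heavily mottled 1. The endoplasmic reticulum chaperone Hspa5, at another probe set than that of the heat shock list, and the secreted Manf ranged over 0.83 and 1.03 log2, both highest in slightly mottled 2, and Pum2, which binds RNA, over 1.41 log2 from mottled 2 to yellow 2.

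The profile of a mouse, as the deviation from the tissue mean, matched its own profile in another tissue best in 4 of 10 mice for liver and kidney, 5 for liver and brain and 6 for kidney and brain. The median r was 0.139, 0.116 and 0.187 with its own profile. With other mice of the same number it was 0.068, 0.049 and 0.060, and with mice of the other number -0.106, -0.056 and -0.105. Part of the likeness between tissues thus ran with the number. The share of probe sets at unadjusted p under 0.05 for the coat was 1.90% in the mean, 2.38% in liver, 2.06% in kidney and 1.45% in brain, while assignments of the coat classes at random gave medians of 3.18%, 3.57%, 3.10% and 3.29%. Those assignments were not balanced over the replicate number as the real classes are, and in the mean they reached 22.2%. Their medians are therefore no measure of chance for balanced classes, and no assignments within number were run for this share.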
